A study of Danio rerio with 2 samples.

How the data were processed

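DNA from a pool of 20 wild-type zebrafish embryos, collected 24 hours after fertilization, was sequenced on a PromethION nanopore instrument, which reads unconverted DNA and calls 5-methylcytosine from the electrical signal. The series holds 2 samples. The nanopore library was analysed here, and the bisulfite library of the same stage was not analysed here. With 1 library there were no replicates and no test between groups, and no p-values across single sites were computed. Permutation p-values are given only for base contexts and for chains of valleys, defined below, within this library.

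Per the file headers, the authors deposited 1 row for each CpG group, with the chromosome, first and last position, number of CpGs, called sites, methylated called sites, methylated fraction and group sequence. The deposited count columns held whole numbers, and both were multiples of the number of CpGs in the group in every row, so the reads behind a group were computed as called sites divided by CpGs. The deposited fraction equalled the ratio of both counts within 0.0005. No groups began less than 11 bases apart, and neighbouring CpGs inside a group shared 1 call. Per the submitters' processing notes, the genome build was GRCz10 (danRer10) and the tools included minimap2 and SAMtools 1.12. Trimmomatic 0.39, Picard 2.3.0 and MethylDackel 0.3.0 were also listed, with no role given. The methylation caller, its call threshold and whether positions count from 0 or 1 were not given in the sources used here, and positions are printed as in the deposited table.

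The tables were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Groups with at least 10 reads entered the results, and the level of a group is its share of methylated reads in percent. Low means at most 20% and high at least 80%. Mean levels give each group the same weight, and pooled levels give each call the same weight. Errors on means are block-jackknife standard errors over 1 Mb blocks (block SE), which describe variation along the genome of this library and not variation between animals. For mitochondrial base contexts, errors are standard errors over groups instead. Errors of valley minus mitochondrial differences combine both kinds. Wilson 95% intervals on pooled shares cover counting error only, since calls from the same read are not independent. They also count each CpG of a group separately, although these share 1 call, and so are too narrow.

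A group with 10 of 10 reads methylated had a Wilson lower bound of 72.2%, and a group with 0 of 10 an upper bound of 27.8%. At 20 reads the bounds were 83.9% and 16.1%. Single groups are therefore described in sets.

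Hypomethylated regions were runs of at least 5 groups whose pooled level over 5 consecutive groups was at most 30%, with no gap above 1 kb. Regions of at least 5 kb are called valleys. Local CpG density is the number of CpGs within 500 bp on either side of a group. For the motif comparisons, groups whose printed sequence held the whole motif on either strand were set against groups with none of the 11 motifs, weighted to the same CpGs per group and local density. Motifs with at least 100 single-CpG groups were also compared in these alone, with and without matching on the flanking bases. Copy number of a group sequence is how often a sequence of at least 20 bases occurred in the table, on either strand, after its first base was removed to leave 4 bases on either side of the outer CpGs. Such sequences are printed in that form. The motif, copy-number and region-dense bin comparisons were chosen after the layout of the table was seen.

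The region caller was tested on simulated calls for 2458992 groups on chromosomes 1 to 5. It recovered 64 of 70 planted regions of 1000 bp, 65 of 65 of 3000 bp and 65 of 65 of 8000 bp, with 0 regions where none was planted. Median length errors were -89, -107 and -122 bp. The simulation was simpler than the data. Background levels were drawn independently for each group, whereas real neighbouring groups were correlated. Planted regions had a flat low level and lay only where groups were closely spaced. The recovered and false counts are therefore not error rates for the real data. The matched comparison returned a mean of -5.04 for a planted difference of -5 points and -30.03 for -30 points, and 19 of 20 intervals covered the planted value in each case. Here too groups were drawn independently, with levels set only by density and the planted difference. This coverage is therefore not that of the real comparisons.

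Alternatives were a minimum of 5 or of 20 reads, leaving out groups above 2 times the median read number, single-CpG groups only, pooled calls, stricter limits for low and high, and region limits of 20% and 40%. An annotation of GRCz10 was not used here, so the planned comparisons by genomic feature, by promoter, by gene list and of valleys at developmental genes were not run. The rule for named genes was to take those at the longest valleys and the extremes of fixed gene lists, and without promoters it named none.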

Results

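Genome-wide CpG methylation was measured in 24-hour zebrafish embryos, a stage at which the body axis has formed and organs are developing. The series set nanopore sequencing beside bisulfite sequencing for base-resolution profiling, with 20 embryos in each sample, and the nanopore library is described here. The table covered 17149049 CpG groups with 23199863 CpGs on chromosomes 1 to 25, and 77.4% of the groups held a single CpG. Groups had a median of 11 reads, with 5th and 95th percentiles of 3 and 19. At least 10 reads were present for 10827999 groups, or 63.1%. The mitochondrial chromosome had 311 groups with a median of 533 reads. No replicate was available for any value, so differences are described within this library only.

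The nuclear genome was highly methylated. The mean level over groups was 81.1% ± 0.0728 (block SE), and the median was 86.7%. High levels were found in 71.4% of groups, intermediate levels in 24.0% and low levels in 4.55%. The pooled level over 204188906 calls was 82.1%. At 10 or more reads, 17.4% of groups were methylated on every read and 2.43% on none.

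Mitochondrial DNA, which in vertebrates carries little CpG methylation, provided a background measured in the same library. Its pooled level was 4.56% (Wilson 95% interval 4.48 to 4.65), from 9688 methylated calls among 212260. Of the 311 mitochondrial groups, 300 were low and 0 were high. Single positions stood higher, with 49.1% at position 1873 (112 of 228 reads) and 37.5% at position 9245 (124 of 331 reads). Levels of a few percent at nuclear sites were therefore within the range recorded on mitochondrial DNA.

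**Figure D1:**
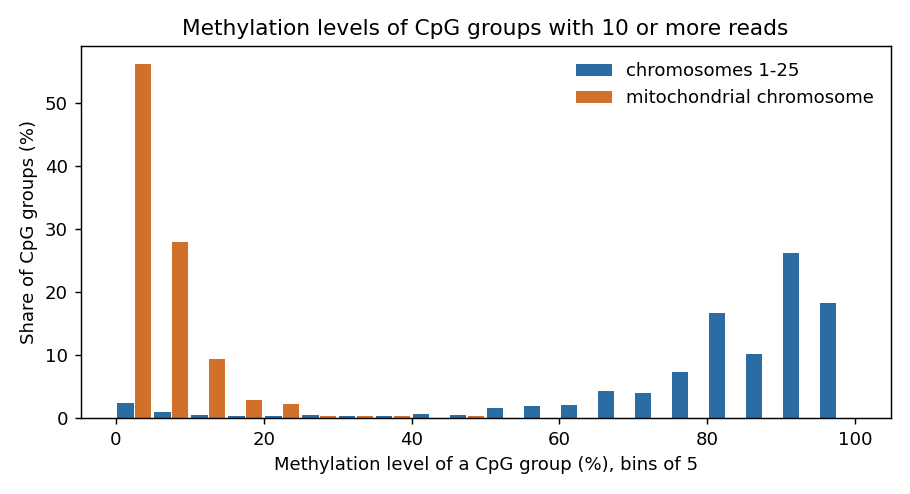
Share of CpG groups (percent) against methylation level in bins of 5 percent, for groups with 10 or more reads on chromosomes 1 to 25 (blue) and on the mitochondrial chromosome (orange). Nuclear groups pile up above 80% with a small peak near 0, whereas 300 of 311 mitochondrial groups lie at or below 20%.

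Methylation varied with CpG density. Groups with 15 to 19 CpGs in the surrounding 1 kb had a mean level of 82.4% ± 0.0441 (block SE), and those with 40 to 59 had 77.7% ± 0.313. The share of low groups rose over the same classes from 2.47% to 12.6%. At still higher density, from 80 to fewer than 120 CpGs, the mean was 86.9% ± 0.627 and the low share 6.91%. The difference from the class of 40 to 59 CpGs was 9.25 ± 0.616 points, and 5.22 ± 1.25 points with a minimum of 20 reads. The densest class, 120 CpGs or more, held 503 groups and its mean of 80.8% ± 7.25 was not resolved from the others. By the number of CpGs sharing a call, the mean was 80.3% ± 0.0616 for 1 CpG, 84.4% ± 0.0959 for 2 and 77.2% ± 0.560 for 8 or more. Low groups made up 4.04% of single-CpG groups and 19% of groups with 8 or more CpGs.

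**Figure D2:**
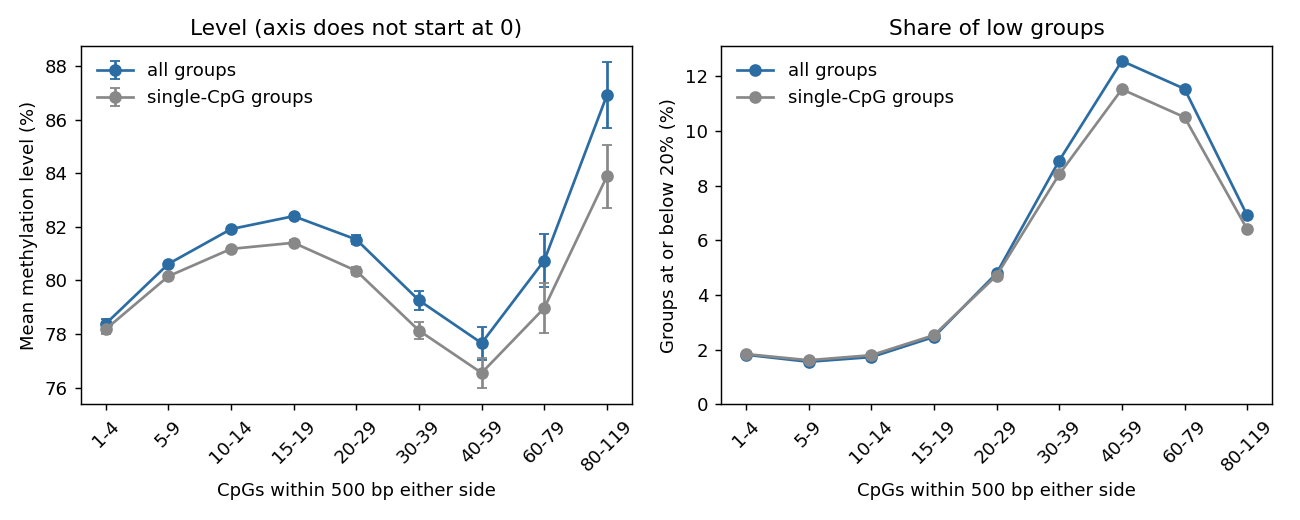
Mean methylation level (left, percent, axis not starting at 0, bars 95% block-jackknife interval) and share of groups at or below 20% (right, percent) by the number of CpGs within 500 bp on either side, for classes of at least 1000 groups. The mean falls to 77.7% at 40 to 59 CpGs and is 86.9% from 80 to fewer than 120 CpGs.

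Low methylation was concentrated in short, discrete stretches of the genome. There were 21328 hypomethylated regions, covering 24.8 Mb or 1.85% of the span. Their median length was 896 bp (quartiles 573 and 1324), and 9041 were at least 1 kb long. These regions held 3.89% of the groups and 78.1% of all low groups. The mean level was 6.76% ± 0.0424 (block SE) inside and 84.1% ± 0.0365 outside. Regions were called from these same levels, so a low inside mean follows from their definition. The pooled level of a region was at most 10% in 18123 regions, or 85.0%. Regions were richer in CpGs, with a median of 31 CpGs per kb around their groups against 19 outside. Beyond the border of regions under 5 kb, the mean level was 27.6% over the first 100 bp, 47.4% over the next 100 bp and 78.5% between 750 and 1000 bp. Borders are set by the level over 5 groups, which can leave low groups outside. Simulated regions with sharp edges were also called shorter than planted. Part of this rise may therefore come from where the caller sets borders. The number of regions rested on depth, and the minimum of 20 reads, which 4.81% of groups met, left 1527.

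Valleys of at least 5 kb numbered 359 and covered 3.29 Mb, and 102 were at least 10 kb long. Their mean level was 5.61% ± 0.0752 (block SE). The longest lay on chromosome 23 from 35943427 to 36024375 (GRCz10), spanned 80.9 kb and 1979 CpGs, and had a pooled level of 4.64% (Wilson 95% interval 4.38 to 4.90). The second lay on chromosome 19 from 20169660 to 20217718, with a level of 4.63% over 48.1 kb. The third lay on chromosome 3 from 23559452 to 23605535, with 3.98% over 46.1 kb. Valleys on chromosome 9 (1957489 to 1989997) and chromosome 5 (49087354 to 49116811) followed, at 32.5 kb and 29.5 kb. The lengths depended on the limits, and the longest valley was 44.2 kb with a region limit of 20%. With the minimum of 20 reads, 18 valleys were called and the longest was 10.4 kb.

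Valleys were clustered along chromosomes. Within 50 kb of another valley lay 83 of the 359, against a mean of 12.2 and a maximum of 30 in 1000 random placements. Placements kept the number of valleys per chromosome and were uniform along it. They did not follow where groups with enough reads or regions were dense, so such unevenness may add to the excess. Some neighbours were pieces of a longer stretch, and with valleys under 5 kb apart joined, 47 of 335 lay within 50 kb of another, against a mean of 10.3 and a maximum of 24. As called, valleys formed 35 chains of at least 2 valleys, and 9 of these had at least 3. With the joining there were 23, and 1 of these had at least 3. The chain with the most valley sequence ran on chromosome 3 from 23519489 to 23643240, where 6 valleys filled 106 of 124 kb. Its mean level was 10.8%, against 62.3% in the 100 kb on either side. Chains on chromosome 23 (99.2 of 103 kb), chromosome 19 (69.7 of 75 kb) and chromosome 9 (67.5 of 78.4 kb) came next.

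**Figure D3:**
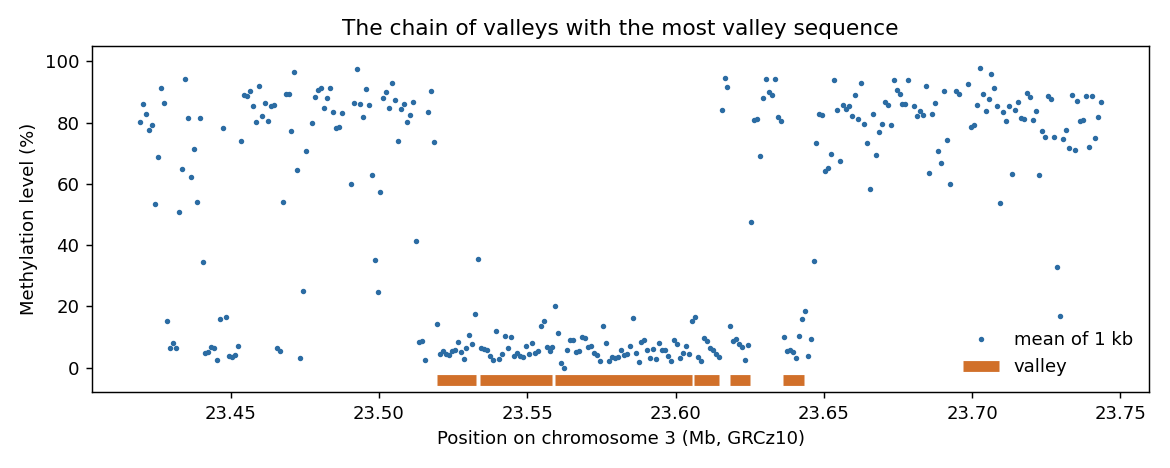
Mean methylation level (percent) of 1 kb steps along chromosome 3 (GRCz10 position in Mb) across the chain with the most valley sequence and 100 kb on either side, with valleys as orange bars. The 6 valleys fill 106 of 124 kb, at a mean of 10.8% over the chain.

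Mean levels differed little between chromosomes. They ranged from 79.8% ± 0.527 (block SE) on chromosome 3 to 82.7% ± 0.323 on chromosome 18. Bins of 1 Mb had a median of 81.3%, with 5% below 76.9% and 5% above 84.6%. The lowest bins began at 23 Mb on chromosome 3 (59.7%), 2 Mb on chromosome 14 (61.1%) and 21 Mb on chromosome 10 (64.8%).

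Chromosome 4, whose long arm is repeat-rich and late-replicating, was divided at 38.3 Mb, the midpoint of its span. The cut was set by length and not by an arm border. Proximal and distal name the parts before and after it. Bins with few regions began before the cut, with 2 regions at 30 Mb and 0 at 31 Mb. The number of groups with at least 10 reads, from which regions are called, also fell there. The distal part had a mean level of 83.7% ± 0.205 (block SE), against 79.5% ± 0.438 in the proximal part and 81.1% ± 0.0740 on the other chromosomes. It held 121 hypomethylated regions, or 3.16 per Mb, and 0 valleys, where the other chromosomes had 16.3 regions per Mb and 357 valleys. With a minimum of 5 reads the densities were 7.36 and 21 per Mb. Regions called in the distal part were unevenly spread, and most lay near its end. The 1 Mb bins from 70 Mb on held 6 to 20 regions each, and those between the cut and 70 Mb at most 5. The bins at 71 to 75 Mb each had more groups with at least 10 reads than any between the cut and 70 Mb. The bins at 41 and 42 Mb had more such groups than that at 70 Mb, but 4 and 1 regions against 6. How far the spread follows the number of such groups was not tested. Low groups made up 1.53% of groups in the distal part and 4.56% of those on the other chromosomes, and 1.66% and 5.01% at 5 or more reads. Depth was lower in the distal part, with a median of 6 reads and 26.3% of groups at 10 or more. The difference from the other chromosomes was 2.61 ± 0.220 points, and -0.671 ± 0.472 points with a minimum of 20 reads, which does not exclude 0.

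**Figure D4:**
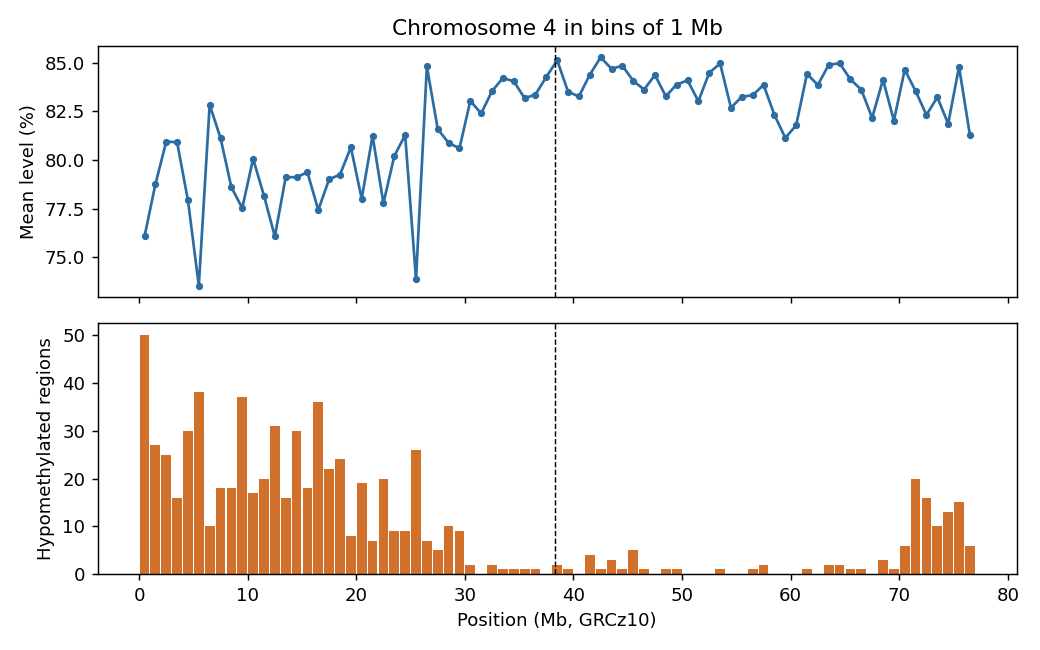
Mean methylation level (top, percent, axis not starting at 0) and number of hypomethylated regions (bottom) in 1 Mb bins along chromosome 4 (GRCz10), with a dashed line at 38.3 Mb. The distal part holds 121 regions, most of them from 70 Mb on, against 620 in the proximal part. Region numbers are not adjusted for the number of groups with at least 10 reads in a bin.

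The bases beside a CpG were related to the level of single-CpG groups. CpGs in GCGC had a mean of 83.2% ± 0.0629 (block SE) and those in GCGA 82.0% ± 0.0589, while CCGG had 77.7% ± 0.0802 and ACGT 77.8% ± 0.0722. Depth differed too, with a median of 13 reads for GCGC, 8 for CCGG and 12 for ACGT. GCGC minus CCGG was 5.54 ± 0.0608 points, and 5.20 ± 0.340 with a minimum of 20 reads. On mitochondrial DNA, the CCGG level was 10.3% ± 2.83 (standard error over groups) over 17 groups and the ACGT level 4.62% ± 0.705 over 16.

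Levels differed between motifs of transcription factors. The site of NRF1, an activator of many broadly expressed genes (GCGCATGCGC), had a mean of 45.3% over 1036 groups, against 83.5% in groups matched for CpG number and density, a difference of -38.2 ± 1.56 points (block SE). Of these NRF1 groups, 47.3% lay in hypomethylated regions, against 8.32% of matched groups. The palindrome TCTCGCGAGA had a mean of 61.1% over 75 groups, a difference of -23.0 ± 5.86 points. Smaller differences were found at GC boxes of SP and KLF factors (-5.23 ± 0.356), hypoxia-inducible factor sites (-4.64 ± 0.189), E-boxes (-3.29 ± 0.0905) and aryl hydrocarbon receptor elements (-3.07 ± 0.104). Sites of ETS factors (1.27 ± 0.149) and CREB or ATF factors (1.67 ± 0.281) and the internal promoter element of tRNA genes (2.90 ± 0.170) stood above their matched groups. E2F sites differed by 0.832 ± 0.441 points, with 0 inside the 95% interval, and YY1 sites by -0.630 ± 0.30. These matched groups did not share the bases beside the CpG, whose relation to the level was of similar size to the smaller differences. In single-CpG groups, the E-box difference was -4.42 ± 0.102 points, and -2.04 ± 0.106 when the flanking bases were matched too. The difference at hypoxia-inducible factor sites went from -7.37 ± 0.197 to -4.88 ± 0.198, at ETS sites from 1.26 ± 0.195 to 3.92 ± 0.197 and at CREB or ATF sites from 5.30 ± 0.176 to 7.78 ± 0.180. YY1 sites stood above their matched groups in single-CpG groups, by 2.1 ± 0.365 and 1.13 ± 0.364 points. Outside hypomethylated regions NRF1 sites differed by -5.43 ± 1.00 points, E2F sites by 0.746 ± 0.252, ETS sites by -0.250 ± 0.105, YY1 sites by 1.15 ± 0.222, tRNA elements by 0.407 ± 0.126 and TCTCGCGAGA by 2.67 ± 1.48 over 49 groups. The differences at GC boxes (-5.96 ± 0.317), hypoxia-inducible factor sites (-4.21 ± 0.137), E-boxes (-3.13 ± 0.0650), aryl hydrocarbon receptor elements (-3.25 ± 0.0763) and CREB or ATF sites (3.17 ± 0.120) kept their sign.

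**Figure D5:**
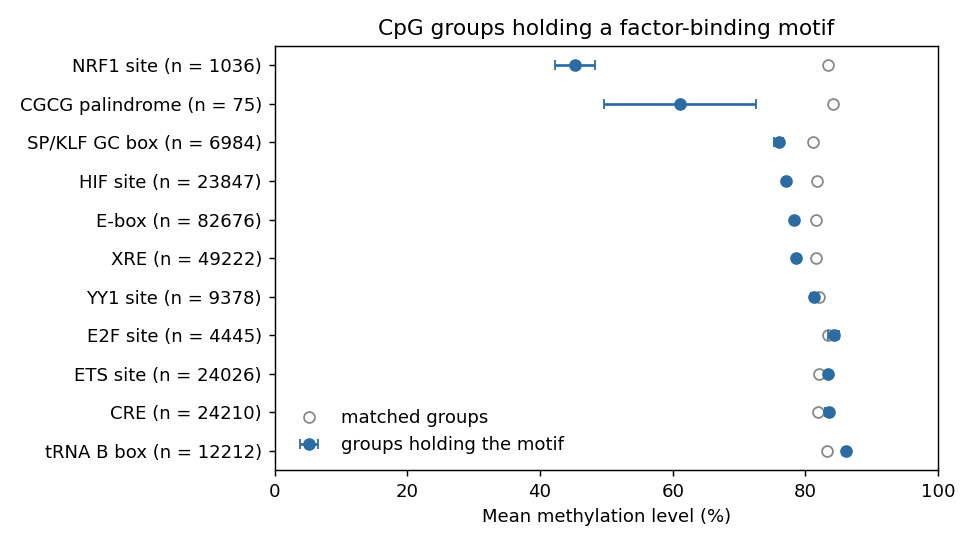
Mean methylation level (percent) of CpG groups that hold each of 11 motifs (blue, bars 95% block-jackknife interval, with n the number of groups) and of groups matched for CpGs per group and density (open circles). NRF1 sites are at 45.3% against 83.5% in matched groups.

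Sequences present in 2 or more copies had higher levels than those found once. Long group sequences found once had a mean of 80.3% ± 0.166 (block SE), and 10.8% of them lay in hypomethylated regions. Sequences in at least 100 but fewer than 1000 copies had a mean of 91.0% ± 0.0788, with 0.932% in such regions. Outside hypomethylated regions the corresponding means were 89.9% and 91.8%. Among 455 sequences with at least 100 measured copies, 445 had a mean of at least 80% and 0 were below 50%. The lowest, AAACCGGAGCACCCGGAGG, had a mean of 60.7% over 1135 copies, with an SD between copies of 22.8 points.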

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

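The comparisons of NRF1 sites, copy number, region density on chromosome 4, longest valley and valley clustering, thinning and matching on flanking bases were chosen after the data were seen. Group size, density and flanking bases were fixed before, but the classes set against each other, and the alternatives, were chosen after. Of 80 alternative values, 30 stayed within the error of the reported one or, for region and valley counts, densities and lengths, within 1.5 times it, 49 moved and 1 reversed. Apart from that reversal every difference among these 80 values kept its direction. Of the motif differences over all groups, only that at NRF1 sites was among them. The difference at YY1 sites changed sign, from -0.63 points over all groups to 2.1 in single-CpG groups. Outside hypomethylated regions, a restriction not among the alternatives, ETS sites went from 1.27 to -0.25 points. There TCTCGCGAGA went from -23 to 2.67 ± 1.48 points over 49 groups, so its sign outside regions was not resolved. Regions are called from the level itself, so this restriction leaves out low groups by design. Of TCTCGCGAGA groups 34.7% lay in regions, against 8.00% of matched groups. For ETS sites these shares were 3.71% and 5.48%. Other causes of these shifts, and the cause of the change at YY1 sites, were not tested. The genome mean was 80.1% with a minimum of 5 reads, 83.6% with 20, 80.3% for single-CpG groups and 82.1% for pooled calls. The low share was 4.96% with 5 reads, 3.39% with 20, 4.58% without groups above 2 times the median read number, 4.04% for single-CpG groups, 3.69% with limits of 10% and 90%, and 4.86% with each group thinned to 10 reads. In the same order, the intermediate share was 26.8%, 17.2%, 24.1%, 27.6%, 51.8% and 18.9%, and the high share 68.2%, 79.4%, 71.3%, 68.4%, 44.5% and 76.3%. The mitochondrial level was 6.37% for single-CpG groups. The distal part of chromosome 4 minus the other chromosomes was 3.86 points with 5 reads, 1.68 for single-CpG groups, 3.08 for pooled calls and, reversed, -0.671 ± 0.472 with 20 reads. With 20 reads, which 4.81% of groups met, there were 1527 hypomethylated regions and 18 valleys, and 44 of the 359 valleys stayed at least 50% covered. Under the other alternatives all 359 did, with 17224 to 27602 regions and 326 to 389 valleys. The longest valley was 10.4 kb with 20 reads and 44.2 kb with a region limit of 20%. With valleys under 5 kb apart joined, 47 lay within 50 kb of another. Regions per Mb in the distal part of chromosome 4 were 7.36 with 5 reads, 0.287 with 20 and 1.85 for single-CpG groups. Groups of 2 CpGs minus groups of 1 were 3.94 points with 20 reads. The densest resolved class minus that with 40 to 59 CpGs per kb were 10.9 points with 5 reads and 5.22 with 20. GCGC minus CCGG was 6.90 points with 5 reads and 5.20 with 20. NRF1 sites minus matched groups were -44.6 points with 20 reads. Matching single-CpG groups on flanking bases too moved 7 of 8 motif differences without changing a sign. Sequences in at least 100 but fewer than 1000 copies minus those found once were 9.97 points with 5 reads and 9.40 with 20. The alternatives foreseen for genomic features, promoters, gene lists and valleys at developmental genes, including valleys of at least 3 kb and other promoter windows, were not run. No paired analysis was possible because 1 library was analysed.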

Other observations

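The tests of NRF1 sites, of valley chains, of tandem copies and of chromosome 4 outside regions at equal depth were chosen after the results were seen, and the others were fixed before. For NRF1 sites, a test outside hypomethylated regions was first set for NRF1, ETS and TCTCGCGAGA sites together, and was narrowed to NRF1 when ETS sites did not lie low. A second test, on neighbouring groups, was added once the first value was known. For the valleys, the requirements for deciding each test were made stricter after the values were seen. The design holds 1 group, so no biological difference between groups was tested.

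Levels of neighbouring groups were related over short distances. Across pairs of groups, which are not independent replicates, Pearson's r was 0.776 at 11 to 20 bp, 0.611 between 200 and 500 bp and 0.0934 between 2000 and 5000 bp. Outside hypomethylated regions it was 0.345 at 11 to 20 bp and 0.0201 between 2000 and 5000 bp, and for groups with at least 20 reads 0.480 and 0.0719. Single-CpG groups outside these regions had an SD of 16 points. Counting error alone gives an SD of 9.77 points, and subtracting its variance leaves an SD of 12.7 points.

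Valleys kept an apparent level of a few percent. In single-CpG groups of whole valleys it was 7.26% ± 0.0860, which is 0.308 ± 0.430 points from the mitochondrial level weighted to the same base contexts. In the middle of valleys the difference was -0.0615 ± 0.439 points, which the rule set beforehand would have read as an effect of valley edges, but with no resolved excess over whole valleys there was nothing for edges to explain. Across the 16 base contexts, mitochondrial and valley levels had a Spearman's rho of 0.185 (permutation p 0.488), under the preset limit of 0.2 but not beyond its spread, since equal true levels with the mitochondrial errors gave -0.0854 to 0.768 in 95% of 2000 simulations. The edge test therefore decides nothing, and caller error by context cannot be told apart from other sources. The mean over valleys was not resolved from this background. Of 359 valleys, 10 had a Wilson lower bound above the pooled mitochondrial level of single-CpG groups (6.37%), the highest at 15.0% on chromosome 3 from 54862220 to 54868697. Valley levels were pooled over groups of all sizes, for which the mitochondrial level was lower, at 4.56%. More valleys had a lower bound above that level, such as that on chromosome 3 from 23519489 to 23532840 (4.68%). All these bounds count CpGs that share 1 call separately. The intervals are therefore too narrow, and which valleys exceed either level is uncertain.

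The distal part of chromosome 4 had a higher level than the other chromosomes. Weighted to the same read numbers from 5 to 20, the difference was 5.41 ± 0.263 points against 4.05 unweighted, so lower depth does not account for it in that range, although it was -0.671 points at 20 or more reads. Among long sequences found once it was 6.91 ± 0.648 points against 5.43 for all long sequences, so it was not confined to exact copies. The test does not decide on repeated sequence more widely, since diverged copies of a repeat count as found once. Of all sequences found once, 10.8% lay in hypomethylated regions, so the restriction also changes the share of such groups. Outside hypomethylated regions it was 0.230 ± 0.186 points, but this value is not weighted for depth, and regions are called from the level itself. Weighted to the same read numbers, 3.52 ± 0.188 of 5.41 points remained outside regions called at 10 reads. Outside regions called at 10 or 5 reads, 2.88 ± 0.167 points remained. How far a scarcity of such regions accounts for the difference therefore stays open.

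NRF1 sites differed from matched groups by -38.2 points. Outside hypomethylated regions the difference was -5.43 ± 1.00 points, but that test leaves out the sites that lie low. Groups 50 to 200 bases from a site, which hold no motif, lay -38.0 ± 1.5 points from their own matched groups, which argues against a calling error at the motif sequence as the whole cause. Among long sequences found once the difference was -47.7 ± 2.16 points, which argues against exact repeated copies. A hypothesis from these values is that many NRF1 sites may lie in unmethylated promoters, which was not tested.

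The longest chains of valleys may lie at the hox clusters, which hold developmental regulators of the body axis. Zebrafish hox clusters lie on 7 chromosomes, and 6 of these were among those of the 7 chains with the most valley sequence, against a mean of 1.6 when the 311 chains, single valleys included, were permuted (permutation p 3e-05). All 7 chromosomes appeared within the first 11, where chromosome 12 had a single valley. The test works by chromosome only, and no gene position was compared.

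The 1 Mb bins at 2 Mb on chromosome 14 and 21 Mb on chromosome 10 held 100 and 61 hypomethylated regions, against a median of 15. Tandem copies of a sequence are a candidate explanation. In their regions, 36.1% and 15.9% of multi-CpG sequences were seen 3 times or more, against a 95th percentile of 5.78% over 418 bins with at least 20 regions. The share was also high on chromosome 22 at 1 Mb (61 regions, 24.8%) and 2 Mb (58 regions, 30.2%). It was 0% in some other dense bins, such as those at 0 Mb on chromosome 4 (50 regions) and 32 Mb on chromosome 3 (48 regions). At 0 Mb on chromosome 22 (50 regions) it was 0.777%. Many regions in a bin therefore do not require such copies.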
